A study of Homo sapiens with 8 samples.

How the data were processed

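Total RNA from 8 samples of HCT116 cells was measured on Affymetrix human gene arrays, 1 array per sample. The samples formed 4 groups of 2, shControl and shCDK8 cells after 40 h of serum starvation and after a further 30 min with 10% serum, and groups were taken from the labels. The deposited values were log2 probe set summaries, made with RMA (a background correction, quantile normalization and summary of probe intensities) per the submitters' processing notes. The version of RMA, the genome build and whether the 8 arrays were normalized together are not given in the sources used here. Biotin-labelled cRNA was prepared by the Affymetrix protocol per the labels' protocols. The number of arrays limits the precision.

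The table held 33297 probe sets. The array annotation listed 21214 of them, of which 19460 were paired with exactly 1 gene and 1754 with several, and 12083 were not listed. Entrez identifiers were looked up in a RefSeq gene table of assembly GRCh38.p14, used for names, chromosomes and gene order alone. Of the probe sets with 1 gene, 19429 matched and 0 symbols changed. Where a gene had several probe sets (769 genes), the one with the highest mean over all arrays was used, which left 18417 genes. The 13837 probe sets paired with no gene or with several were fitted separately and are not named as genes. The probe set of the targeted gene is among them and is given by its identifier.

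Values were used on the deposited scale with no further normalization and no filter. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with 4 residual degrees of freedom and moderated variances (prior degrees of freedom 5.49). The 7 contrasts were serum against starved in each line, shCDK8 against shControl at each time, the difference between the lines' serum responses, and the averages of the serum and of the line contrasts. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes within each contrast, and genes with an adjusted p below 0.05 are said to have risen or fallen. Errors of changes are standard errors of the model, and errors of levels are SDs. Overlaps were tested with the one-sided Fisher's exact test.

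A total of 23 gene lists was written down from general knowledge, each with at least 5 measured genes. They were tested with limma's camera with a preset correlation of 0.01, and P-values were adjusted over the lists within each contrast. Camera with an estimated correlation and fry served as alternatives. Some lists share genes. The named genes were the measured members of the Mediator kinase module and, per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the groups. For averaged contrasts the change had to have the same sign in both lines or times. Where none passed in a direction, the 5 with the smallest p were named as not passing. Up to 4 members per list with the largest changes, those past the threshold first, were added. Groups, contrasts, tests, lists, this rule and the alternatives below were fixed before the data were examined.

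The alternatives were an intensity trend in the variance prior, a fit of the compared arrays alone, the replicate number as a block, genes above the 25th percentile of mean level, cyclic loess, centring of each array on its median, the mean of a gene's probe sets, a minimum change of 1.5-fold, and leaving out each of the 8 arrays; 1 further block was added later. Leaving out an array left 1 group with a single array, which was assumed to vary like the other groups. The procedure was tested on simulated data with 50 genes shifted by each of 4 sizes in the serum contrast of shControl cells. It recovered 64% of genes shifted by 0.5 on the log2 scale, 96% of those shifted by 1 and 100% of those shifted by 2 or 3. Of 191 genes called, 11 (5.76%) were false. In the difference of responses, camera called 2 of 100 random unshifted lists at an unadjusted p below 0.05. The simulated genes varied independently of each other, so the simulation does not test lists whose members vary together. Figures were drawn with matplotlib 3.10.9.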

Results

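Gene expression was measured in HCT116 cells, an established human colorectal cancer line with wild-type p53. The cells expressed either a control short hairpin RNA (shControl) or a hairpin directed against CDK8 (shCDK8), the kinase of the dissociable kinase module of Mediator, the complex that connects transcription factors to RNA polymerase II. Both lines were starved of serum for 40 h and were harvested then or after 30 min in medium with 10% fetal bovine serum. This gave 4 groups of 2 arrays, 8 arrays in all, and the small number of arrays limits the precision of each value. Levels are on the log2 scale, n is 2 arrays per group throughout, and 18417 genes were tested. The median level of an array lay between 6.44 and 6.51, and duplicate arrays correlated across genes with r between 0.997 and 0.998. The first principal component held 61.3% of the variance and separated the lines. The second held 16.6% and separated starved from serum-treated cells. The labels do not say whether duplicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Each arm also had a single hairpin, so a difference between the lines holds both the knockdown and anything else in which the lines differed.

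The targeted gene was examined first. CDK8 is represented by probe set 7968199, which the annotation pairs with both CDK8 and ADRA1B, and the value therefore belongs to the probe set. It read 9.22 ± 0.02 (SD) in starved shControl cells, 9.20 ± 0.02 in serum-treated shControl cells, 7.04 ± 0.07 in starved shCDK8 cells and 7.05 ± 0.01 in serum-treated shCDK8 cells. The level was thus 4.53-fold lower in shCDK8 cells before serum (log2 -2.18 ± 0.07 SE, adjusted p = 6.53e-08) and 4.45-fold lower after it (log2 -2.15 ± 0.07, adjusted p = 8.12e-08). Serum moved it by -0.01 in shControl and 0.01 in shCDK8 cells, neither past the threshold (adjusted p = 0.972 and 0.963). None of the 6 other measured members of the kinase module passed the test in either line comparison. CDK19, the paralog of CDK8, differed by 0.23 ± 0.07 in starved cells (adjusted p = 0.0646) and by 0.03 after serum, and CCNC, the cyclin partner of CDK8, differed by -0.17 and -0.24. MED12, MED12L, MED13 and MED13L, the other module subunits, differed by 0.04, 0.06, -0.07 and -0.12 in starved cells. CDK19 passed in starved cells with an intensity trend in the variance prior (adjusted p = 0.0289) and with dim genes left out (0.0413; range over its alternatives up to 0.294). CCNC passed after serum under the same alternatives (0.0120 and 0.0461) and without either starved array of shControl (0.0446 each; range up to 0.240), and it fell by 0.21 on the log2 scale in the average over both times (adjusted p = 0.0214), a call that ended without 1 of 5 arrays: starved array 1 of either line (adjusted p = 0.0650 for shControl and 0.0754 for shCDK8), serum array 1 of shControl (0.0570), its serum array 2 (0.0666) and serum array 2 of shCDK8 (0.0672).

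**Figure D1:**
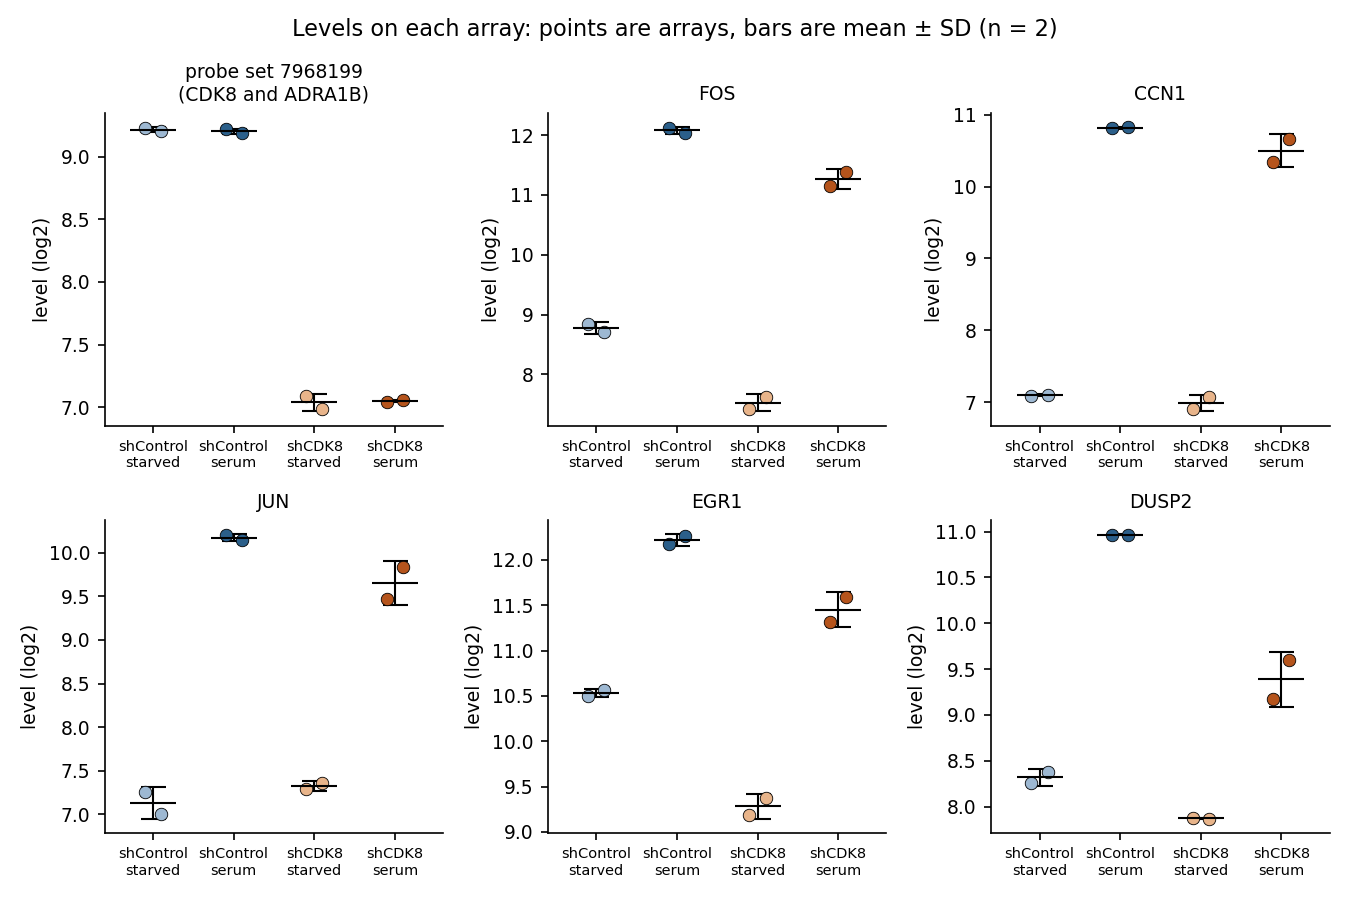
Level on each array (log2, y axis) of the probe set paired with CDK8 and ADRA1B and of 5 serum-induced genes in the 4 groups; points are arrays and bars are mean ± SD (n = 2). The probe set lies between 9.19 and 9.23 in the shControl arrays and between 6.99 and 7.09 in the shCDK8 arrays, and serum-treated groups lie above starved ones for each of the 5 genes.

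The first question was which genes respond to 30 min of serum in control cells. In shControl cells the 10 largest rises were all of immediate-early list genes, which are transcribed without new protein synthesis. CCN1, a secreted matrix-associated protein, rose 13.1-fold (log2 3.72 ± 0.10 SE, adjusted p = 2.91e-07). FOS and JUN, subunits of the transcription factor AP-1, rose 9.88-fold (3.30 ± 0.10, adjusted p = 3.79e-07) and 8.24-fold (3.04 ± 0.12). FOS read 8.78 ± 0.10 (SD) in starved and 12.08 ± 0.05 in serum-treated cells. FOSB rose 8.31-fold, the transcription factor ATF3 9.05-fold (3.18 ± 0.21) and the orphan nuclear receptors NR4A3, NR4A1 and NR4A2 10.0-fold, 7.21-fold and 6.80-fold. DUSP1 and DUSP2, phosphatases that switch off MAP kinases, rose 7.37-fold and 6.27-fold. In all, 78 genes rose and 7 fell, with 25 rising at least 2-fold and none falling that far. The falls were small: the largest were those of HEATR4 (log2 -0.53 ± 0.08, adjusted p = 0.0153), OR2W5P (-0.52) and XAGE-4 (-0.49 ± 0.06). The total of 85 genes was 46 without starved array 1 of shControl, 33 without its starved array 2 and 40 without its serum array 2, and 128 with an intensity trend.

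By gene list, 32 of the 47 measured immediate-early genes rose in shControl cells and none fell (41 rose adjusted over the list alone; camera adjusted p = 2.01e-101, and 0.0227 with an estimated correlation). Of 24 feedback inhibitors of MAPK and NF-kB signalling, 7 rose (11 adjusted over the list alone; adjusted p = 2.01e-19, and 0.0115 with an estimated correlation), and 6 of these also stand in the immediate-early list. ZFP36, which destabilises AU-rich mRNAs, rose 3.70-fold and DUSP5 2.37-fold. Of 26 p53 targets, 5 rose (5 adjusted over the list alone; adjusted p = 2.48e-04, and 0.219 with an estimated correlation): the polo-like kinases PLK2 (log2 1.12 ± 0.07) and PLK3 (0.74), the cytokine GDF15 (1.09), the pro-apoptotic PMAIP1 (0.72) and GADD45A. The 21 other listed p53 targets did not pass. Of 17 TGF-beta and BMP targets, 3 rose (5 adjusted over the list alone; adjusted p = 3.33e-05, and 0.0624 with an estimated correlation), namely ID1, ID3 (0.80 ± 0.10) and KLF10 (0.64 ± 0.06). All 3 are also immediate-early list members, as are SRF (0.62 ± 0.08) and CCN1, the 2 of 20 SRF and MRTF targets that rose (2 adjusted over the list alone; adjusted p = 2.17e-04, and 0.1005 with an estimated correlation). CXCL8 and LIF, a chemokine and a cytokine, were the 2 of 20 NF-kB targets that rose (0.83 and 0.61; 2 rose and 2 fell adjusted over the list alone; list adjusted p = 0.346). The stress-induced DDIT4 (0.65) and DDIT3 rose among 22 ATF4 targets (5 adjusted over the list alone; adjusted p = 2.24e-05, 0.239 with an estimated correlation and 0.0563 in fry), and ANKRD37 (0.86) and ADM (0.43) among 24 hypoxia and glycolysis genes (2 adjusted over the list alone; adjusted p = 1.94e-04, 0.354 with an estimated correlation and 0.114 in fry). Of the 33 named genes that passed, 12 and 16 lost the threshold without starved arrays 1 and 2 of shControl, 14 and 15 without its serum arrays 1 and 2, and 3 to 5 without an array of shCDK8 (adjusted p up to 0.379). HEATR4, OR2W5P, XAGE-4, PLK3, ID1, ID3, SRF, CXCL8, LIF, DDIT3, DDIT4 and ADM were among them.

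Further lists moved little in shControl cells, with no member past the threshold over all genes. Elongation factors (list mean 0.06, adjusted p = 0.00631, and 0.451 with an estimated correlation) and cholesterol genes (adjusted p = 0.0141, and 0.381 with an estimated correlation) were called upward, and blood and endothelial markers downward (adjusted p = 0.0108, and 0.389 with an estimated correlation). The cholesterol call ended without starved array 2 (adjusted p = 0.0507) or serum array 2 (0.0582) of shControl, and the call of the blood and endothelial markers without that serum array (0.148) or with dim genes left out (0.0691). All 3 calls also ended with cyclic loess (adjusted p = 0.136 for elongation factors, 0.193 for cholesterol genes and 0.0964 for the markers) and in fry (0.320, 0.173 and 0.173). In neither line did a member of the Wnt, E2F, mitotic, core Mediator, heat shock, interferon, ribosomal protein, housekeeping, colonic or mesenchymal lists pass over all genes, and of these lists the mitotic list alone was called, upward in shCDK8 cells (adjusted p = 8.15e-06, 0.437 with an estimated correlation and 0.190 in fry). In shCDK8 cells ATF4 targets (adjusted p = 0.00243, and 0.397 with an estimated correlation), FOXO targets (0.0340, and 0.2001 with an estimated correlation) and elongation factors (0.0437, and 0.520 with an estimated correlation) were also called upward, with the transcriptional regulator CITED2 (0.65 ± 0.10, adjusted p = 0.0435) the 1 member that passed. CITED2 lost the threshold without any 1 of 7 arrays, all but serum array 1 of shCDK8 (adjusted p up to 0.307). The calls ended without serum array 2 of shCDK8 (adjusted p = 0.0811, 0.109 and 0.0845), those of FOXO targets and elongation factors also without its starved array 1 (0.0903 and 0.630), and that of elongation factors without its serum array 1 (0.109). The call of ATF4 targets ended in fry (0.152), that of FOXO targets with dim genes left out (0.0965), and that of elongation factors with dim genes left out (0.0815), cyclic loess (0.253), the mean of probe sets (0.0688) and fry (0.356).

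In shCDK8 cells the same comparison again gave immediate-early genes as the largest rises. FOS rose 13.4-fold (log2 3.74 ± 0.10 SE, adjusted p = 2.33e-07), CCN1 11.4-fold (3.51 ± 0.10), FOSB 7.45-fold, NR4A2 6.84-fold, ATF3 6.39-fold and JUN 5.03-fold. EGR1, a zinc-finger transcription factor, rose 4.49-fold (2.17 ± 0.10, adjusted p = 6.02e-06). CCN2, a secreted protein related to CCN1, rose 2.07-fold (1.05 ± 0.08, adjusted p = 3.96e-04). Of the 47 immediate-early genes 25 rose and none fell (41 rose adjusted over the list alone; adjusted p = 3.73e-81, and 0.0346 with an estimated correlation). Of the 24 feedback inhibitors 6 rose (9 adjusted over the list alone; adjusted p = 1.03e-14, and 0.0200 with an estimated correlation), DUSP2 by 2.86-fold and ZFP36 by 3.25-fold. Of the 6 feedback inhibitors that rose, 5 also stand in the immediate-early list. Of the SRF and MRTF targets 3 rose, CCN1, CCN2 and SRF, all 3 also immediate-early list members. Adjusted over the list alone 3 rose (camera adjusted p = 8.15e-06, and 0.0649 with an estimated correlation). Of the p53 targets GDF15 (0.68), PLK2 (0.63) and PMAIP1 (0.54) rose (5 adjusted over the list alone; adjusted p = 1.15e-04, and 0.183 with an estimated correlation), and no TGF-beta target passed over all genes, with ID3 at 0.49 and KLF10 at 0.26 (5 rose adjusted over the list alone; adjusted p = 1.41e-04, and 0.0649 with an estimated correlation). In total 46 genes rose, 22 of them at least 2-fold, and XAGE-4 fell (-0.42 ± 0.06, adjusted p = 0.0301). The total of 47 was 23 and 25 without starved arrays 1 and 2 of shCDK8, 24 without its serum array 2, 28 in a fit of the 4 shCDK8 arrays alone and 100 with an intensity trend. Of the 21 named genes that passed, 6 and 7 lost the threshold without starved arrays 1 and 2 of shCDK8, 2 and 6 without its serum arrays 1 and 2, and 2 to 4 without an array of shControl (adjusted p up to 0.307), among them SRF, GDF15, PLK2, PMAIP1, CITED2 and XAGE-4.

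Between the lines, 40 genes rose and 1 fell in both serum comparisons, where independent lists of these sizes would share 0.195 and 0.000380 genes (one-sided Fisher's exact test, p = 5.15e-94 and 3.80e-04). These comparisons share no array, but both use 1 estimate of each gene's spread from all 8 arrays. The shared total of 41 was 22 to 27 without 1 of 6 arrays (each starved array of either line, serum array 2 of shControl and serum array 2 of shCDK8), 24 when each line was fitted alone and 71 with an intensity trend. Averaged over both lines, 126 genes rose and 14 fell, led by CCN1 (3.61 ± 0.07) and FOS (3.52 ± 0.07). Of the 126, 39 stand in the immediate-early list. The total of 140 was 89 to 93 without 1 of 4 arrays (starved array 1 or serum array 2 of shCDK8, starved array 2 or serum array 2 of shControl), 236 with an intensity trend and 48 with a minimum change of 1.5-fold.

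**Figure D2:**
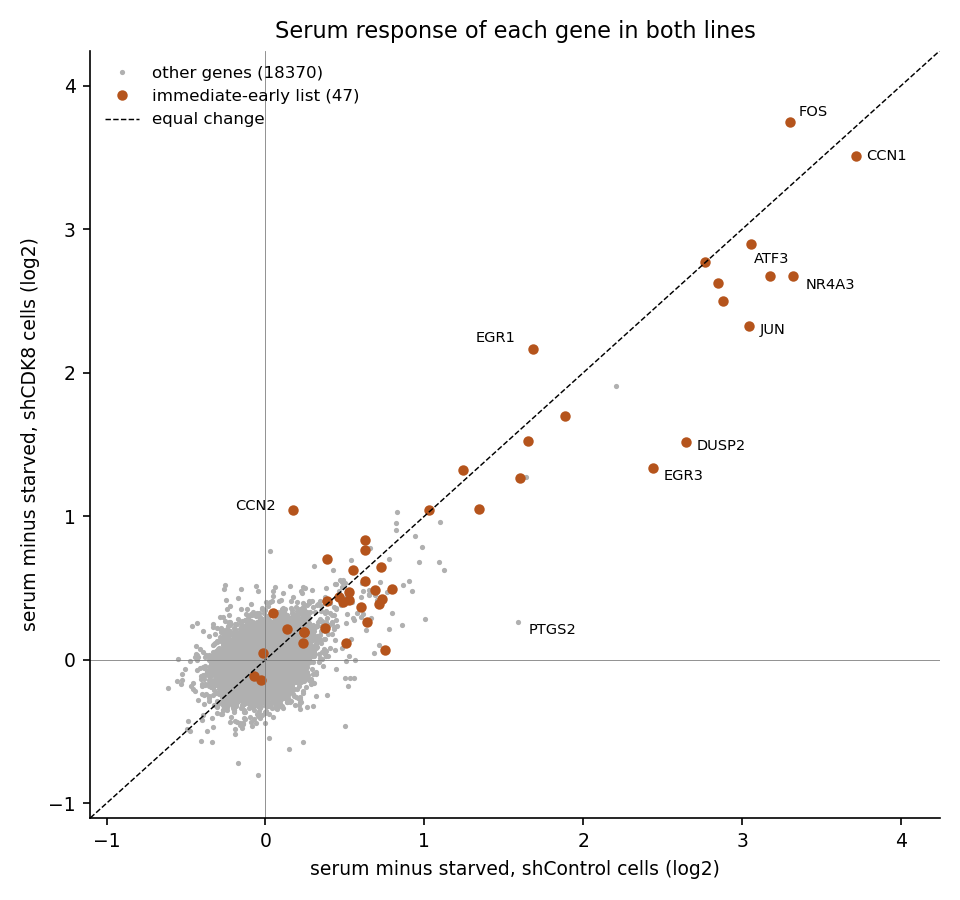
Change after 30 min of serum (log2, serum minus starved) of each of the 18417 genes in shControl cells (x axis) and in shCDK8 cells (y axis), with the 47 immediate-early list genes in orange and a dashed line of equal change. CCN1 has the largest change in shControl cells (3.72) and FOS in shCDK8 cells (3.74), while DUSP2 (2.65 and 1.52) and PTGS2 (1.59 and 0.27) lie below the line and CCN2 (0.17 and 1.05) above it; no gene passed the test of the difference.

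The next question was how CDK8 knockdown bears on the serum response, tested as the difference between the lines' responses. No gene passed limma's test of the difference after Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 in limma's test there were 703 of 18417 genes, a smaller share than the 0.05 expected if no response differed. With an intensity trend 7 genes passed after adjustment. The smallest adjusted p, 0.203, was shared by PTGS2, the inducible cyclooxygenase (1.59 in shControl and 0.27 in shCDK8 cells; difference -1.32 ± 0.18 SE), DUSP2 (2.65 and 1.52; -1.13 ± 0.17), the synaptic immediate-early gene ARC (-0.68 ± 0.10), UGT2B10 (0.65), LOC728024 (-0.70) and CCN2 (0.17 and 1.05; 0.87 ± 0.12). EGR3, a relative of EGR1, rose by 2.44 and 1.34 (difference -1.10 ± 0.17, adjusted p = 0.295). PTGS2, DUSP2, ARC, LOC728024, CCN2 and EGR3 were among the 7 with the trend, as was PLK2 (-0.50). Without serum array 2 of shCDK8, 1 gene, DUSP2, passed. As a list, the 47 immediate-early genes rose by a mean of 1.20 in shControl and 1.06 in shCDK8 cells. The difference of -0.14 passed camera with its preset correlation (adjusted p = 1.05e-05), though not with an estimated correlation (adjusted p = 0.973) or in fry (adjusted p = 0.867). It was -0.05 without serum array 1 of shCDK8 (adjusted p = 0.254) and -0.23 without its serum array 2. Over the 126 genes called in the averaged serum comparison, the median response was 0.60 in shControl and 0.48 in shCDK8 cells, and 84 of them had the smaller response in shCDK8 cells. The median difference of -0.11 ranged from -0.23 to -0.02 over the 16 ways of taking 1 array per group (SD 0.07). It was -0.20 over the genes that also changed 1.5-fold. Leaving out serum arrays 1 and 2 of shCDK8 gave -0.04 and -0.23, serum arrays 1 and 2 of shControl -0.17 and -0.18, starved array 1 of shControl -0.18 and starved array 1 of shCDK8 -0.16.

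In starved cells the lines differed at many more genes than serum changed. SEMA3A, a secreted axon-guidance ligand, was 46.0-fold higher in shCDK8 cells (log2 5.52 ± 0.07 SE, adjusted p = 1.26e-10), reading 11.84 ± 0.01 (SD) against 6.32 ± 0.07. TNFSF18 and TNFSF4, ligands of the tumour necrosis factor family, were 26.7-fold and 21.5-fold higher, TM4SF18 16.3-fold, the adhesion receptor ADGRF1 9.90-fold, the growth factor FGF9 9.47-fold, BMP4 7.24-fold, PLK2 5.65-fold, CEMIP 5.47-fold and the Notch ligand JAG1 5.45-fold. The amino acid transporter SLC38A5 was 8.64-fold lower (-3.11 ± 0.11, adjusted p = 1.79e-07) and RGS2, a regulator of G protein signalling, 7.21-fold lower. SPTSSB, a subunit of serine palmitoyltransferase, SCG2, the peptidase DPP4 and the actin-associated PALLD were 7.02-fold, 6.25-fold, 6.04-fold and 4.54-fold lower. AFF4, a scaffold of the super elongation complex, was 3.91-fold lower, as were DEPDC1 (4.04-fold), MPP7 (3.23-fold) and the RAF kinase ARAF (3.16-fold). In total 1313 genes were higher and 1157 lower, 109 and 43 of them at least 2-fold. Under a minimum of 1.5-fold 356 were higher and 184 lower, 540 in all. Leaving out a single starved array gave 1599 (shControl array 1), 1588 (shControl array 2), 1468 (shCDK8 array 1) and 1488 (shCDK8 array 2).

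Cell-cycle lists were lower in starved shCDK8 cells. Of 26 mitotic genes 25 fell and none rose (25 adjusted over the list alone; camera adjusted p = 3.62e-24, and 0.116 with an estimated correlation), including the phosphatase CDC25C (log2 -1.18 ± 0.09), the mitotic kinesins KIF20A (-0.97) and KIF11 (-0.85) and the anaphase activator CDC20 (-0.93 ± 0.07). Of 30 E2F and DNA replication genes 18 fell and none rose (24 fell and 1 rose adjusted over the list alone; adjusted p = 2.60e-12, and 0.116 with an estimated correlation), among them TK1 (-0.62), E2F8 (-0.59), POLA1 (-0.57) and CCNA2 (-0.56). Of 24 hypoxia and glycolysis genes 13 fell and 1 rose (13 and 2 adjusted over the list alone; adjusted p = 9.35e-06, and 0.254 with an estimated correlation), such as P4HA1 (-1.02 ± 0.11), BNIP3 (-0.78) and SLC2A3 (-0.73), and the glucose transporter SLC2A1 rose (1.78 ± 0.07). Of 27 elongation factors 7 fell and SUPT4H1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0247, and 0.603 with an estimated correlation). That list's call also ended without starved array 1 of shControl (adjusted p = 0.0784) or of shCDK8 (0.290). Among 13 housekeeping reference genes 4 fell (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.00824, 0.270 with an estimated correlation and 0.0627 without starved array 1 of shControl), with TFRC at -0.92 ± 0.07 and B2M at -0.47.

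Other lists were higher in starved shCDK8 cells. Of 22 Wnt and beta-catenin targets 11 rose and none fell (11 rose and 1 fell adjusted over the list alone; adjusted p = 2.08e-08, and 0.0418 with an estimated correlation), led by BMP4 (log2 2.86 ± 0.10), CEMIP (2.45), the ubiquitin ligase RNF43 (1.28 ± 0.06) and CD44 (1.03). Of 17 TGF-beta and BMP targets 8 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 4.56e-08, and 0.0418 with an estimated correlation): BMP4 again, the pseudoreceptor BAMBI (1.82 ± 0.08), PMEPA1 (1.05) and SKIL (0.96) among them. Of 26 p53 targets 13 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 2.08e-08, and 0.103 with an estimated correlation), led by PLK2 (2.50), TP53I3 (1.00 ± 0.07), TIGAR (0.78) and TP53INP1 (0.76). Of 20 SRF and MRTF targets 6 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00324, and 0.131 with an estimated correlation), CALD1 the most (0.72). Of 19 cholesterol and fatty acid synthesis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 9.58e-04, and 0.254 with an estimated correlation), including FASN (0.61), HMGCS1 (0.56), LSS (0.53) and MVD (0.50). The immediate-early list went both ways, with 14 of 47 members lower and 10 higher (15 and 10 adjusted over the list alone; adjusted p = 0.603). FOS and EGR1 were lower (-1.25 ± 0.10 each), and HES1 and KLF4 higher (1.18 ± 0.13 and 1.07 ± 0.10). Keratins KRT18 (0.55) and KRT8 (0.44) were the 2 of 18 colonic epithelium markers that rose, and SPARC (1.30 ± 0.10) and FN1 (0.39) the 2 of 17 mesenchymal markers. FN1 did not pass without starved array 2 of shCDK8 (adjusted p = 0.0519). Neither list passed, and in both the median was below 0 and the mean above it. The remaining lists did not pass in starved cells: feedback inhibitors (4 of 24 rose and 4 fell), NF-kB targets (2 of 20 rose), FOXO targets (3 of 19 rose and 2 fell), ATF4 targets (2 of 22 rose and 2 fell), heat shock genes (2 of 12 rose), interferon genes (5 of 23 rose and 3 fell), ribosomal protein genes (2 of 30 rose) and core Mediator subunits (1 of 24, MED20, rose, a call that ended without 1 of 6 arrays, the starved ones of either line and the serum ones of shControl, with an adjusted p of up to 0.204 over its alternatives). None of the 12 blood and endothelial markers passed, nor did that list (adjusted p = 0.653). The calls of the ATF4 target SESN2 and the heat shock gene DNAJA1 ended whichever array was left out. Those of the ATF4 targets XBP1 and DDIT3 ended without some arrays, as did those of other named genes.

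**Figure D3:**
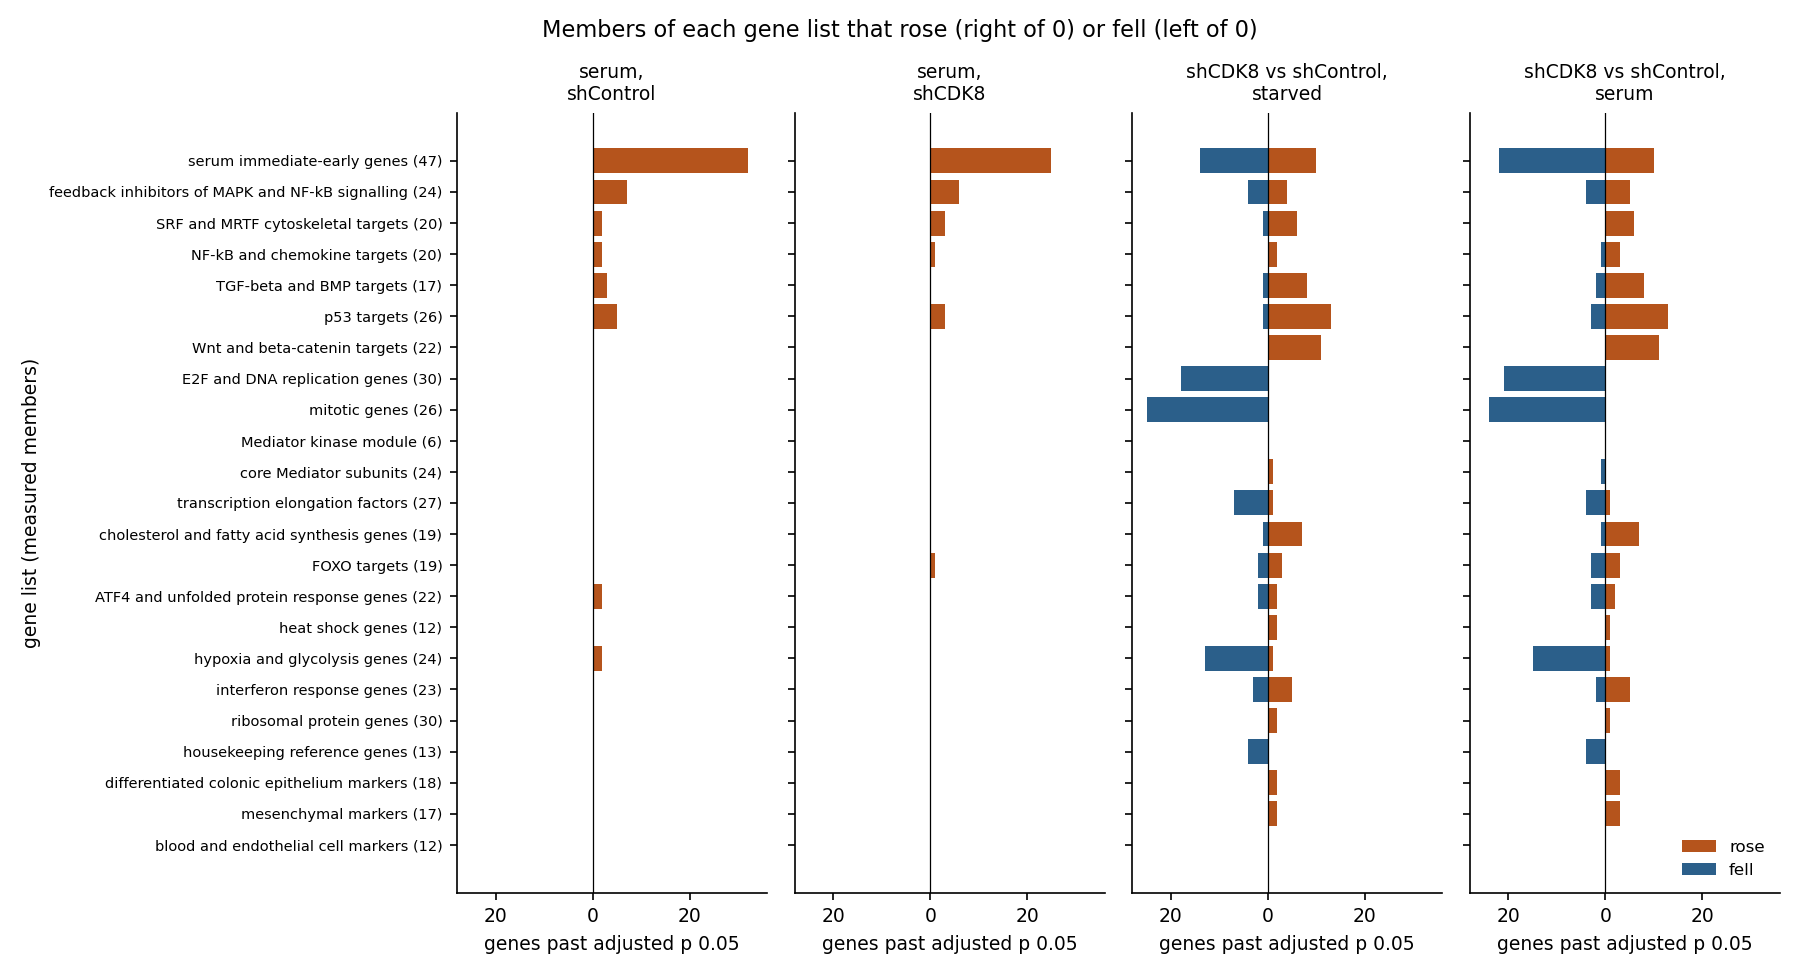
Number of members of each of the 23 gene lists that rose (orange, right of 0) or fell (blue, left of 0) past an adjusted p of 0.05 over all genes, in 4 comparisons; the number of measured members stands in parentheses. Immediate-early genes lead the serum panels with 32 and 25 rises, and mitotic genes lead the falls in shCDK8 cells with 25 before and 24 after serum.

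After serum the differences between the lines were much like those before it. SEMA3A was 46.4-fold higher in shCDK8 cells (log2 5.54 ± 0.07 SE, adjusted p = 1.22e-10), TNFSF18 32.0-fold, TNFSF4 27.1-fold and the epithelial transcription factor EHF 6.79-fold. SPTSSB (7.59-fold), SLC38A5 (7.35-fold), DPP4 (5.68-fold), RGS2 (5.62-fold) and AFF4 (4.19-fold) were lower. In total 1419 genes were higher and 1205 lower, 116 and 52 of them at least 2-fold. Of these, 1042 were higher and 835 lower at both times, where independent lists would share 101 and 75.7. The starved and serum comparisons use different arrays, but 1 estimate of each gene's spread from all 8 arrays. Of 47 immediate-early genes 22 were lower and 10 higher (27 and 11 adjusted over the list alone; adjusted p = 5.54e-04, 0.535 with an estimated correlation and 0.0646 in fry). DUSP2 was 2.99-fold lower (-1.58 ± 0.12, adjusted p = 2.40e-05), ZFP36 2.09-fold and EGR3 2.08-fold lower, and KLF4 2.60-fold higher. CCN2 differed by 0.03 before serum (adjusted p = 0.886) and was 1.87-fold higher after it (0.90 ± 0.08, adjusted p = 1.09e-04). Under a minimum of 1.5-fold 381 genes were higher and 182 lower, 563 in all. Without serum arrays 1 and 2 the total was 1452 and 1484 for shControl and 1696 and 1710 for shCDK8.

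The lists also stood much as before serum. Mitotic genes fell in 24 of 26 cases (25 adjusted over the list alone; adjusted p = 1.93e-20, and 0.115 with an estimated correlation), CDC25C by 1.23 and CDC20 by 0.95 on the log2 scale. E2F and replication genes fell in 21 of 30 (25 fell and 1 rose adjusted over the list alone; adjusted p = 3.43e-12, and 0.115 with an estimated correlation), and hypoxia and glycolysis genes in 15 of 24 with SLC2A1 rising (15 and 2 adjusted over the list alone; adjusted p = 1.17e-07, and 0.184 with an estimated correlation). Wnt targets rose in 11 of 22 with none falling (11 rose and 3 fell adjusted over the list alone; adjusted p = 8.89e-08, and 0.0505 with an estimated correlation), SOX9 by 2.57-fold. p53 targets rose in 13 of 26 and fell in 3 (17 and 4 adjusted over the list alone; adjusted p = 2.36e-06, and 0.115 with an estimated correlation), and the 3 that fell were GDF15, PLK3 and PMAIP1. TGF-beta and BMP targets rose in 8 of 17 and fell in 2 (9 and 2 adjusted over the list alone; adjusted p = 3.36e-07, and 0.0505 with an estimated correlation). SRF and MRTF targets rose in 6 of 20 (10 rose and 2 fell adjusted over the list alone; adjusted p = 8.77e-04, and 0.115 with an estimated correlation), cholesterol and fatty acid genes in 7 of 19 with SQLE falling (7 and 1 adjusted over the list alone; adjusted p = 0.00306, and 0.295 with an estimated correlation). Elongation factors fell in 4 of 27 with SUPT4H1 rising (5 and 1 adjusted over the list alone; adjusted p = 0.0115, and 0.522 with an estimated correlation), and housekeeping reference genes in 4 of 13 (4 fell and 1 rose adjusted over the list alone; adjusted p = 0.0145, and 0.330 with an estimated correlation). The call of GUSB, 1 of these 4 housekeeping genes, ended whichever array was left out. Calls of other named genes after serum ended without some arrays. Averaged over both times, 2215 genes were higher and 2082 lower in shCDK8 cells, 4297 in all. With each array centred on its median the balance turned, to 2000 higher and 2378 lower. It turned likewise at the single times, to 1219 and 1293 in starved cells and 1281 and 1398 after serum. The averaged total was 535 with a minimum of 1.5-fold, 357 of them higher and 178 lower. SEMA3A was the furthest above (5.53 ± 0.05) and SLC38A5 the furthest below (-2.99 ± 0.08).

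**Figure D4:**
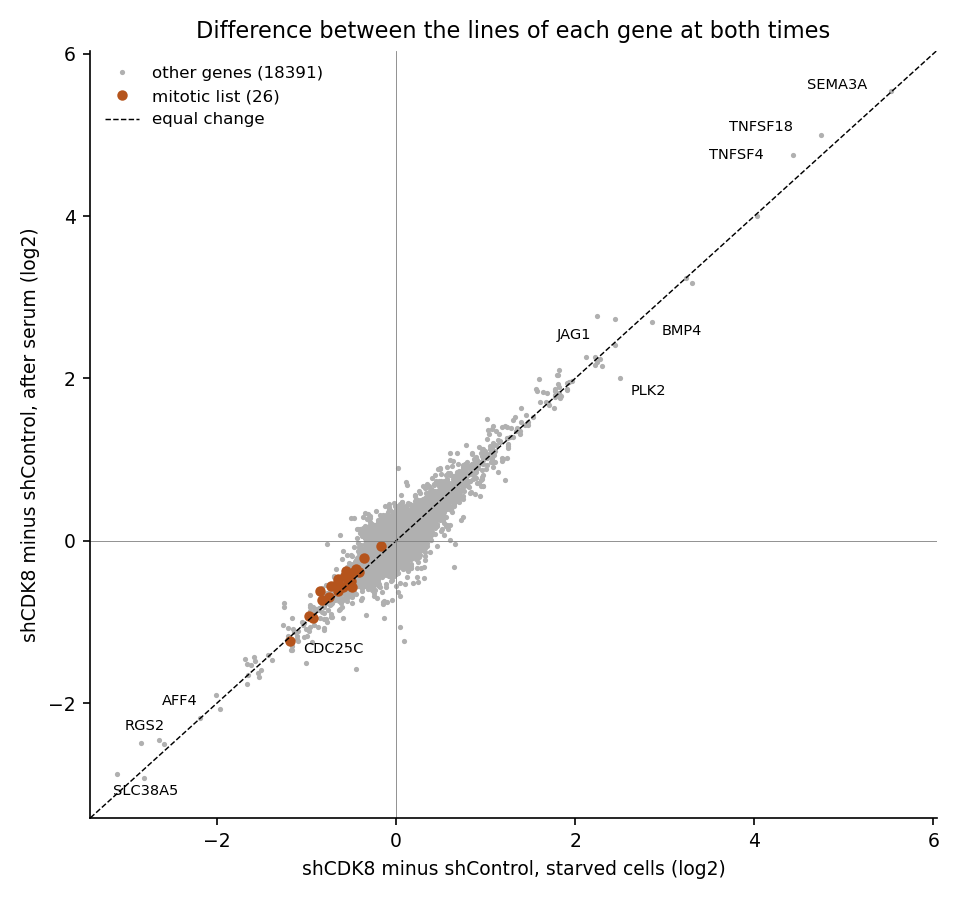
Difference between shCDK8 and shControl cells (log2) of each of the 18417 genes in starved cells (x axis) and after serum (y axis), with the 26 mitotic list genes in orange and a dashed line of equal difference. SEMA3A lies at 5.52 and 5.54, SLC38A5 at -3.11 and -2.88, and the mitotic genes that passed, 25 before and 24 after serum, lie below 0.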

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

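The tests of single arrays, saturation, starting levels, chromosome copies, cycling cells and other differences between the lines were chosen only after the results were seen.

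In 3 gene lists the serum response differed between the lines by a test of the difference itself. The immediate-early list had a smaller mean response in shCDK8 cells (difference -0.143 on the log2 scale, camera adjusted p = 1.05e-05). The mitotic list had a larger one (0.0827, adjusted p = 0.0190) and the hypoxia and glycolysis list a smaller one (-0.0796, adjusted p = 0.0319). With an estimated correlation none of the 3 passed (adjusted p = 0.973 for each), nor in fry (0.867 for each). The mitotic call ended without starved array 1 of shControl (adjusted p = 0.366), its serum array 2 (0.0906), starved array 1 of shCDK8 (0.806) or its serum arrays 1 and 2 (0.163 and 0.0556). The hypoxia call ended without starved array 2 of shControl (0.599), its serum arrays 1 and 2 (0.0874 and 0.0906), starved array 2 of shCDK8 (0.2002) or its serum array 1 (0.617). Among the 13837 probe sets outside the gene tests, 4 passed the threshold for serum in shControl cells. Between the lines 58 passed in starved cells (34 higher and 24 lower in shCDK8 cells) and 63 after serum (35 higher and 28 lower), the targeted probe set among the lower ones.

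The size of the smaller immediate-early response in shCDK8 cells depended on which serum array of that line was left out. With duplicates, leaving out either array moves the difference equally to opposite sides, so neither array can be marked as the deviant one. Without serum array 2 of shCDK8 the mean difference was -0.233. Without serum array 1 of shCDK8 the mean difference was -0.0532 and the adjusted p 0.254, and that array's list mean was 9.35 against 9.53 for its duplicate. A comparison by brightness decided nothing about saturation: the brighter members differed from the dimmer ones by -0.0243 (SE over genes 0.105). Saturation of the brightest probe sets would shrink most the response of the line that read higher after serum. That line was shControl, with a list mean of 9.63 (SD 0.0007) against 9.44 (SD 0.13) in shCDK8 cells. For the list mean, these values argue against saturation as the source of the smaller response in shCDK8 cells. A different starting level was not decided. It predicts a mean difference near 0 for members with nearly equal starting levels. The 23 members with the smaller starting difference had -0.208 (SE over genes 0.0814), and the 24 others had -0.0816 (SE over genes 0.0656). The direction goes against the prediction, but not by the margin set for the test. These errors over genes treat genes as independent and leave out the variation between arrays. A reduced serum response after loss of CDK8 may be present, and with 2 arrays per group it cannot be told apart from variation between single arrays.

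Mitotic and DNA replication genes were lower in shCDK8 cells at both times, with a median of -0.51 over the mitotic list. With an estimated correlation neither list passed camera in the averaged comparison (adjusted p = 0.107 for each). That setting was the 1 of 16 alternatives that ended either call. Copy differences of whole chromosomes did not account for the fall of the mitotic list, since the largest median difference of any of 23 chromosomes with at least 100 genes was 0.0288. Copy differences of parts of chromosomes would not move such a median and were not tested. For the mitotic list, a shift of all genes at that level was excluded, as the lowest of 10000 random lists matched on level had a median of -0.198. The replication list was not tested in this way. Fewer cycling cells, from loss of CDK8 or another difference between the lines, stays open: the fall of 25 of 30 replication genes is part of the pattern and decides nothing.

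The lines differed at many genes, 1877 of which changed the same way at both times. In a 2-group fit, 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave 4034 genes, and the highest of the others gave 27. Those others hold arrays of both lines on each side, so the line difference widens their spread. A first rank among only 35 splits cannot exclude chance. The same fit for serum gave 27 genes and ranked 2 of 35, behind the split by line with 4034, which is a structure of the design, while the other 33 splits gave 0. The share of splits therefore does not decide for serum either. The lines shared 40 rises on separate arrays, against 0.195 for independent lists (one-sided Fisher's exact test, p = 5.15e-94). That test counts genes as independent, and both comparisons use 1 estimate of each gene's spread from all 8 arrays. With each line fitted alone, the shared total of rises and falls was 24 instead of 41. Loss of CDK8 and another difference between the lines, such as an effect of the hairpin on other transcripts, cannot be told apart, because each arm had 1 hairpin.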

How the results depend on the processing

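The crossed replicate block was chosen only after the data were seen. With an intensity trend the counts were 128 (serum in shControl), 100 (serum in shCDK8), 7 (difference of responses), 236 (serum averaged) and 71 (shared serum calls). In fits of the compared arrays alone serum in shCDK8 gave 28 genes and the shared calls 24. With a minimum of 1.5-fold the counts were 540 (lines, starved), 563 (lines, after serum), 535 (lines, averaged) and 48 (serum averaged), and the median difference of responses was -0.20. The difference of -0.14 for the immediate-early list did not pass with an estimated correlation (adjusted p = 0.973) or in fry (0.867). Leaving out single arrays gave 33 to 85 genes for serum in shControl, 23 to 51 for serum in shCDK8, 1468 to 2315 and 1452 to 2564 for the lines before and after serum, 0 to 1 for the difference of responses, 89 to 135 for serum averaged, 22 to 39 shared calls, -0.230 to -0.0352 for the median difference and -0.233 to -0.0532 for the list. Equal replicate numbers did not mark shared deviations (correlations from -0.186 to 0.126), and the replicate block gave 75, 41, 2298, 2545, 0, 123 and 4161 genes in the order of the 7 contrasts. The crossed block gave 2359 genes for the lines in starved cells. Of the values that answer a comparison, 115 stayed within their bounds, 39 moved and 3 lost the threshold. List calls held in 944 cases and were lost in 128. These losses were uneven: camera with an estimated correlation ended 58 list calls and kept 9, and fry ended 19 and kept 48. Lists with a positive estimate lost calls under that camera setting, such as mitotic genes for serum in shCDK8 cells (estimate 0.384). Lists with a negative estimate also did, such as TGF-beta targets for serum in shControl cells (-0.0485) and FOXO targets for serum in shCDK8 cells (-0.0177). The losses therefore cannot be put down to correlation between list members alone. Calls of named genes held in 4927 cases and were lost in 494, and named genes that had not passed did so in 80. No called value changed direction.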

Other observations

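The test of neighbouring genes was chosen only after the result was seen.

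Several serum-induced genes lay outside the fixed lists, and those named here were chosen after their values were seen. Averaged over both lines, THBS1, a matrix glycoprotein, rose by 2.06 ± 0.10 on the log2 scale (adjusted p = 4.13e-06), with 2.21 in shControl and 1.91 in shCDK8 cells. BHLHE40, a transcriptional repressor that responds to growth factors, rose by 1.46 ± 0.08 (1.64 and 1.28). The small GTPase GEM rose by 1.03 ± 0.10, the kinase NUAK2 by 0.89 ± 0.09 and the AP-1 family member FOSL2 by 0.74 ± 0.09. Of 8 variant U1 small nuclear RNA genes, 5 rose, but their near-identical copies leave open which of them did.

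Between the lines, the genes named here were again chosen after their values were seen, and no family was tested. SEMA3C (1.93 ± 0.04), SLIT2 (1.92 ± 0.06) and the ephrin EFNB2 (2.22 ± 0.05) were higher in shCDK8 cells on the average of both times. The cyclin-dependent kinase CDK6 (1.81 ± 0.07), the nuclear receptor PPARG (1.79 ± 0.06) and the growth factor receptor IGF1R (1.66 ± 0.06) were also higher. The transcription factors MEF2C (-1.65 ± 0.08) and NFIB (-1.59 ± 0.07) were lower.

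Differences between the lines at single immediate-early genes after serum may in part have been present before it. Whether this holds for the list mean stays open, since the change of the mean with serum did not pass with an estimated correlation (adjusted p = 0.973). The mean line difference was -0.05 in starved cells (14 of 47 genes lower and 10 higher, camera adjusted p = 0.603) and -0.19 after serum (22 lower and 10 higher, adjusted p = 5.54e-04, and 0.535 with an estimated correlation). Across the 47 list genes the line difference after serum followed that in starved cells, measured on other arrays (Pearson's r = 0.808, Spearman's rho = 0.774, permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without HES1 and FOS r was 0.794. Genes are not independent replicates, and across all genes r was 0.874, so that the relation is not particular to this list.

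Genes that differed at least 2-fold between the lines at both times (97 higher and 40 lower) included 11 pairs of neighbours changing the same way, a question raised by TNFSF18 and TNFSF4. None of 10000 shuffled gene orders gave as many (highest 6, one-sided permutation p = 1e-04, the smallest they can give). The pair that raised the question is counted among the 11. The pairs are not all separate, since ODAD2 and KLRC3 each stand in 2 of them. Shuffling also takes neighbouring genes to be otherwise unrelated. In 3 pairs the names share their first 3 letters, TNFSF18 with TNFSF4 and 2 pairs of KLRC genes, where similar sequences or a shared transcript might bring the values together. The 8 others include SLX4IP with JAG1, DDX60L with PALLD and MPP7 with ODAD2. A local change of chromosome structure or of shared regulation in 1 line is a candidate explanation, and was not tested further.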
